A study of Mus musculus with 32 samples.

How the data were processed

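RNA was measured by sequencing in synovium and cartilage of C57BL/6 mice, in control mice and in mice of the MMS model. Per the submitters' processing notes, RNA was extracted with Trizol, libraries were made at BGI, and reads were aligned with HISAT2 to mm10. The authors deposited 1 table of normalised values per tissue, and no read counts were used here. The synovium table gives FPKM per the file headers, for 1178 genes in 18 samples. The deposited cartilage table gives a normalised signal whose unit is not stated, for 1606 genes in 14 samples. The tables do not give total reads per sample, so depth is unknown and no counting interval or detection limit could be given. The number of replicates, 3 per synovium group and 2 per cartilage group, limits the precision.

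Both tables hold a selected part of the genes, and the selection rule is not stated. The lowest value was 0.550 in synovium and 0.500 in cartilage. The filter on low values, at least 1 in as many samples as the smallest group, removed no gene. In 1 synovium gene and 2 cartilage genes the symbol had been turned into a date or a number, and these were tested but not named. No pair of samples shared more than 0.509% identical values in synovium or 0.560% in cartilage. Gene positions came from GENCODE vM21 on GRCm38, and Wisp2 is annotated there as Ccn5.

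Samples were grouped by tissue and by the group name in their labels. Replicate numbers are not stated to pair samples, so no pairing was used. Values were analysed as log2 of the value plus 1, as deposited, without further normalisation. Each tissue was fitted with all its groups in limma 3.58.1 (R 4.3.3) with a trend in the variance. Each MMS group, R1 and R2 was compared with Control, and R1 and R2 were compared with MMS D14, which makes 15 comparisons. P-values were adjusted by Benjamini and Hochberg over all genes of a comparison, and an adjusted p under 0.0500 was called. A set of 30 gene lists for cell types and processes was tested with camera in limma, where at least 5 members were measured. Camera used a preset correlation of 0.0100, and its p-values were adjusted over the lists of a comparison. A second run estimated the correlation from the residuals.

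Groups, lists, comparisons, tests, the alternatives not described as added and the rule for naming genes were fixed before the data were examined. For each comparison with Control, the rule took the genes past the test with all samples of the group on one side of all Control samples. It further required an average expression above the median of the tested genes and a symbol that is not a predicted model. Of these it named the 8 with the largest rises and the 8 with the largest falls. For R1 and R2 against MMS D14 it named 5 in each direction. From each gene list, 2 to 4 members with the smallest adjusted p could be named, and a list gene could be named for its value where it did not pass. Comparisons of R2 with R1 and a set of synovium libraries that stand apart were added after the values were seen. Direct comparisons of successive MMS groups were also run at that stage, and their results are not reported here.

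The alternatives were centring each sample on its median, a pseudocount of 0.10, no filter, limma without the trend, the replicate number as a block, only the 2 groups compared, and leaving out each library in turn. A stricter count also required an absolute log2 change of at least 1. Chosen after seeing the data were a term for the synovium library set, leaving that set out, and centring in the gene list tests. Other splits of the synovium samples into groups of the same sizes were tested in the same way, with 100 drawn at random where there were more. The fit was tested on simulated data with known changes. In synovium it recovered 70% of simulated changes of 1 on the log2 scale, with 3.90% false calls. In cartilage it recovered 88% with 4.44% false calls. These rates hold for that setting and do not carry over to the real tables, which hold selected genes. Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.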

Results

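RNA sequencing measured gene expression in synovium and in cartilage of C57BL/6 mice, in control mice and in mice of a model that the labels call MMS. The labels do not spell out MMS, R1 or R2, and the numbers after D carry no stated unit, so the group names are used as given. Synovium had 18 samples in 6 groups, with n = 3 in each of Control, MMS D3, MMS D7, MMS D14, R1 and R2. Cartilage had 14 samples in 7 groups, with n = 2 in each of the same groups and MMS D28. The synovium table held FPKM for 1178 genes and the cartilage table held a signal of unstated unit for 1606 genes. Sequencing depth is not given in the tables used here and is unknown. The listed values summed to 70104.5 to 132996 per synovium sample and 108504 to 149830 per cartilage sample, which are sums over selected genes and not depths. Levels below are mean ± SD with the n just given, and changes are log2 ratios of the value plus 1. Adjusted p-values come from limma, over all genes of the tissue. The labels do not say that replicates are separate animals, so every p-value measures only the spread between samples.

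Both tables hold selected genes, and the rule of selection is not stated. In synovium, 1155 of 1178 genes (98.0%) differed at least 1.5-fold between the mean of MMS D14 and that of Control, against 49.7% for MMS D3. In cartilage, 1590 of 1606 genes (99.0%) did so between MMS D28 and Control, against 8.59% for R2. Counts in those comparisons, and in the comparisons with MMS D14 in synovium, are therefore at least partly fixed by the selection. Every other comparison with Control uses the same Control samples, so its counts may carry part of the selection as well, to an unknown extent. The gene list tests take their background from the same selected genes. The median log2 change of all synovium genes against Control was -0.34 in MMS D3, -0.65 in MMS D7, -1.08 in MMS D14, -0.38 in R1 and -0.38 in R2. Against MMS D14 it was 0.65 in R1 and 0.64 in R2. In cartilage it was -0.49 in MMS D28 and -0.19 in R1, and within 0.1 of zero in the other comparisons. No gene named by the rule in the methods changed sign when each sample was centred on its median. Counts of list members are over all genes tested, and the count adjusted over the list alone is given where it differs. Members missing from the selected genes could not be counted, so such counts hold only for the members measured. In synovium MMS D14 against Control (1142 of 1178 genes called) they are partly fixed by the selection, and in cartilage MMS D28 against Control (1563 of 1606) largely so. With a correlation estimated from the residuals, 4 of the 34 list calls by camera in synovium held, all for the matrix protease and inhibitor list, in MMS D7, MMS D14, R1 and R2 against Control. In cartilage 0 of 31 held, with 5 of the 120 camera tests at an unadjusted p under 0.05.

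**Figure D1:**
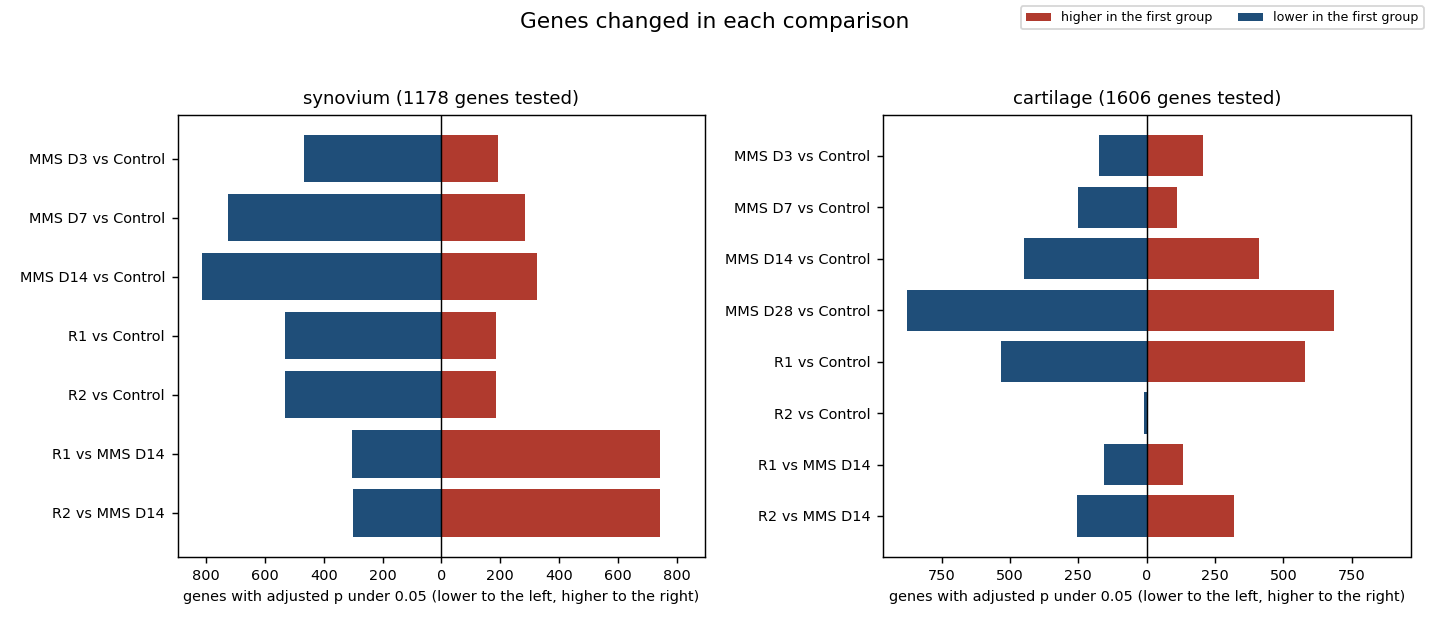
Bars show the number of genes called higher or lower (limma, adjusted p under 0.05) in each comparison, by tissue. Synovium MMS D14 against Control had 326 higher and 816 lower genes, and cartilage R2 against Control had 1 higher and 11 lower.

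The first synovium comparison asks which genes differ between MMS D3 and control mice. Spp1, which encodes the matrix phosphoprotein osteopontin, rose from 2.85 ± 0.221 to 79.0 ± 76.3 (log2 change 3.95), with all MMS D3 samples above all Control samples. Lox, a lysyl oxidase that cross-links collagen, rose from 17.2 ± 2.14 to 170.2 ± 28.6 (log2 change 3.23). Timp1, an inhibitor of matrix metalloproteinases, rose from 72.5 ± 20.2 to 526 ± 296 (log2 change 2.73), and the chemokine gene Ccl8 rose from 6.72 ± 2.15 to 84.1 ± 35.7 (log2 change 3.42). Clic5, a gene of the synovial lining fibroblast list, fell from 123 ± 18.5 to 20.7 ± 1.88 (log2 change -2.51), and Acss2, an acetate-activating enzyme of lipid synthesis, fell from 83.6 ± 29.2 to 11.7 ± 2.62 (log2 change -2.70). The other largest rises were in Nt5dc2 (3.72), Wisp2 (3.44), Slc39a14 (2.48) and Tnfaip6 (2.46). The other largest falls were in Hist2h2aa1 (-2.63), Retnla (-2.45), Orm1 (-2.37), Adrb3 (-2.33), Tmem45b (-2.11) and Rbp4 (-2.10). Adjusted p-values of these 16 genes ran from 1.18e-09 to 0.0209, and every gene named by this rule here and in the later comparisons had all samples of its group on one side of all samples of the reference group. The call for Retnla (adjusted p = 0.0209, 0.00417 to 0.106 over its alternatives) ended without MMS D3 replicate 1 (0.106), without Control replicate 1 (0.0603) and without the 5 libraries that stand apart (0.0523). In all, limma called 659 of 1178 genes, 192 higher and 467 lower.

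All 10 cell cycle genes rose in MMS D3 synovium (median log2 change 1.62, camera adjusted p = 1.03e-06, adjusted p = 0.219 with an estimated correlation). The most significant were Rrm2, a ribonucleotide reductase subunit, 9.50 ± 5.75 against 1.61 ± 0.226 (adjusted p = 0.000186), and the replication helicase gene Mcm5, 10.2 ± 5.56 against 2.54 ± 0.351 (adjusted p = 0.000631). In the fibrillar collagen and fibrosis list 12 of 20 members rose (median log2 change 0.78, camera adjusted p = 3.61e-07, adjusted p = 0.196 with an estimated correlation), among them Postn, which encodes periostin, 305 ± 93.8 against 78.3 ± 6.13. In the matrix protease and inhibitor list 7 of 12 members rose and 1 fell (median log2 change 0.70, camera adjusted p = 0.00204, adjusted p = 0.104 with an estimated correlation), and Ctsk, a collagen-degrading cathepsin, rose from 79.8 ± 15.6 to 201 ± 68.6 (log2 change 1.29). In the Wnt signalling list 4 of 5 members rose and 1 fell (median log2 change 0.99, camera adjusted p = 0.0114, adjusted p = 0.196 with an estimated correlation), where Sfrp4, a secreted Wnt antagonist, fell from 62.8 ± 13.2 to 32.6 ± 17.9 (log2 change -1.03). In the synovial lining fibroblast list 4 of 5 members fell (median log2 change -1.61, camera adjusted p = 0.0201, adjusted p = 0.117 with an estimated correlation), including Hbegf, an EGF-family growth factor, from 162 ± 8.37 to 47.7 ± 10.6 (log2 change -1.76). That list call ended without the 5 libraries that stand apart (adjusted p = 0.0687, 0.00921 to 0.0687 over its alternatives). In the interferon response list 5 of 5 members fell (median log2 change -1.11, camera adjusted p = 0.0913, adjusted p = 0.593 with an estimated correlation), with Cxcl9, an interferon-induced chemokine, at 4.65 ± 1.43 against 14.5 ± 3.68. The adipocyte list was not called (median log2 change -0.52, camera adjusted p = 0.159, adjusted p = 0.857 with an estimated correlation), although 7 of 17 members fell, and Adipoq, which encodes adiponectin, fell from 1715 ± 163 to 1069 ± 233 (log2 change -0.70).

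For MMS D7 synovium the comparison with Control puts the same question to the next D number. Cthrc1, a secreted protein of injured and fibrotic matrix, rose from 6.24 ± 1.46 to 243 ± 55.1 (log2 change 5.07), and Spp1 rose from 2.85 ± 0.221 to 159 ± 76.1 (log2 change 5.24). Postn rose from 78.3 ± 6.13 to 767 ± 271 (log2 change 3.22), and Tnc, which encodes the matrix glycoprotein tenascin C, rose from 2.32 ± 0.234 to 44.3 ± 4.99 (log2 change 3.77). Adrb3, the adrenergic receptor of fat cells, fell from 78.7 ± 11.6 to 8.29 ± 5.76 (log2 change -3.40), and Myoc, which encodes myocilin, fell from 89.3 ± 14.4 to 16.3 ± 8.26 (log2 change -2.48). Further rises were in Nt5dc2 (4.16), Ccl8 (4.05), Wisp2 (3.73) and Mfap4 (3.36). Further falls were in Retnla (-2.65), Rbp4 (-2.17), Cyp2e1 (-2.13), Thrsp (-2.10), Pnpla3 (-2.07) and Acss2 (-2.03). These 16 genes had adjusted p-values of 3.14e-10 to 0.00760. Retnla (adjusted p = 0.00760, 0.00175 to 0.0870 over its alternatives) was not called without MMS D7 replicate 3 (0.0566) or without the 5 libraries that stand apart (0.0870). The test called 1010 of 1178 genes, 284 higher and 726 lower. Within the fibrillar collagen and fibrosis list 20 of 20 members rose (median log2 change 1.75, camera adjusted p = 1.40e-13, adjusted p = 0.0851 with an estimated correlation). In the cell cycle list 10 of 10 members rose (median log2 change 2.35, camera adjusted p = 2.03e-06, adjusted p = 0.295 with an estimated correlation), and Ccnb2, a mitotic cyclin, rose from 1.38 ± 0.286 to 18.4 ± 3.34 (log2 change 3.02). Within the matrix protease and inhibitor list 9 of 12 members rose and 1 fell (median log2 change 1.58, camera adjusted p = 6.26e-05, adjusted p = 0.0256 with an estimated correlation), with Mmp14, a membrane-bound collagenase, at 198 ± 44.5 against 54.3 ± 3.73. In the Wnt signalling list 4 of 5 members rose (median log2 change 1.73, camera adjusted p = 0.00173, adjusted p = 0.131 with an estimated correlation). In the adipocyte list 14 of 17 members fell (median log2 change -1.20, camera adjusted p = 0.0139, adjusted p = 0.591 with an estimated correlation), among them Dgat2, the last enzyme of triglyceride synthesis, from 543 ± 91.2 to 147 ± 22.8 (log2 change -1.88). All 5 interferon response genes and all 14 fatty acid metabolism genes fell, but camera called neither list (adjusted p = 0.331 and 0.0583).

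In the MMS D14 synovium, the selection of genes was closest to the comparison tested. Spp1 (chromosome 5, 104435118 to 104441050, GRCm38) rose from 2.85 ± 0.221 to 802 ± 416 (log2 change 7.59). Cthrc1 (chromosome 15, 39076932 to 39087121) rose from 6.24 ± 1.46 to 352 ± 31.3 (log2 change 5.63), Tnc rose from 2.32 ± 0.234 to 154 ± 45.8 (log2 change 5.51), and Thbs4, a matricellular thrombospondin, rose from 15.9 ± 3.43 to 362 ± 34.6 (log2 change 4.44). Fmod, which encodes the collagen-binding proteoglycan fibromodulin, rose from 10.8 ± 7.66 to 362 ± 93.6 (log2 change 5.10). Retnla (chromosome 16, 48842551 to 48844461), a secreted protein of fat tissue and of alternatively activated macrophages, fell from 192 ± 43.3 to 3.04 ± 1.45 (log2 change -5.63). Pck1, a gene of glycerol and glucose synthesis, fell from 596 ± 91.2 to 52.6 ± 8.27 (log2 change -3.48). The remaining largest rises were in Nt5dc2 (4.39), Mfap4 (3.98) and Tnfaip6 (3.84). The remaining largest falls were in Adrb3 (-4.62), Cyp2e1 (-3.80), Ces1d (-3.60), Tmem45b (-3.55), Rbp4 (-3.38) and Ces1f (-3.37). Ces1d and Ces1f are close copies of one gene family, and how shared reads were assigned is not stated. Adjusted p-values of these 16 genes lay between 5.40e-10 and 2.29e-05. A total of 1142 genes of 1178 were called, 326 higher and 816 lower, a number partly fixed by the selection.

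All 17 measured adipocyte genes fell in MMS D14 (median log2 change -2.22, camera adjusted p = 0.00380, adjusted p = 0.568 with an estimated correlation). Cidec, a lipid droplet protein gene, fell from 905 ± 171 to 140.4 ± 12.9 (log2 change -2.67), Pnpla2, the main triglyceride lipase gene, fell from 1044 ± 211 to 178 ± 11.6 (log2 change -2.53), and Lipe, the hormone-sensitive lipase gene, fell from 565 ± 42.4 to 103 ± 13.7 (log2 change -2.45). All 14 fatty acid metabolism genes fell (median log2 change -1.65, camera adjusted p = 0.0497, adjusted p = 0.568 with an estimated correlation), with Slc27a1, a fatty acid transporter, at 55.0 ± 2.52 against 225 ± 40.4. The camera call for that list (adjusted p 0.0219 to 0.0573 over its alternatives) ended without Control replicate 1 (0.0509), without MMS D14 replicate 1 (0.0543) and without MMS D14 replicate 2 (0.0573). All 20 fibrillar collagen and fibrosis genes rose (median log2 change 2.36, camera adjusted p = 3.51e-12, adjusted p = 0.115 with an estimated correlation), including Col5a2, a fibrillar collagen chain, from 77.1 ± 3.89 to 457 ± 2.34 (log2 change 2.55). In the matrix protease and inhibitor list 10 of 12 members rose and 2 fell (median log2 change 1.83, camera adjusted p = 0.000113, adjusted p = 0.0318 with an estimated correlation), and Mmp2, a gelatinase gene, rose from 117 ± 15.7 to 940.2 ± 54.6 (log2 change 3.0). Every one of the 10 cell cycle genes rose (median log2 change 2.72, camera adjusted p = 1.65e-05, adjusted p = 0.377 with an estimated correlation), with Prc1, a cytokinesis gene, at 23.3 ± 9.38 against 1.60 ± 0.142. In the Wnt signalling list 4 of 5 members rose (median log2 change 2.38, camera adjusted p = 0.00380, adjusted p = 0.188 with an estimated correlation), and Dkk3, a secreted dickkopf protein gene, rose from 7.64 ± 0.815 to 97.7 ± 15.2 (log2 change 3.51). Lists too small for camera also held changes: the osteoclast gene Acp5 fell from 369.5 ± 71.3 to 106 ± 10.7 (log2 change -1.78) while Ctsk rose from 79.8 ± 15.6 to 314 ± 46.5 (log2 change 1.97). Skeletal muscle genes were high in single libraries, with Myl1 at 136 in MMS D14 replicate 3 and 117 in Control replicate 2. In the erythroid list 5 of 5 members fell (median log2 change -1.08, camera adjusted p = 0.799, adjusted p = 0.873 with an estimated correlation), with Hba-a1 and its near-identical copy Hba-a2 among them.

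**Figure D2:**
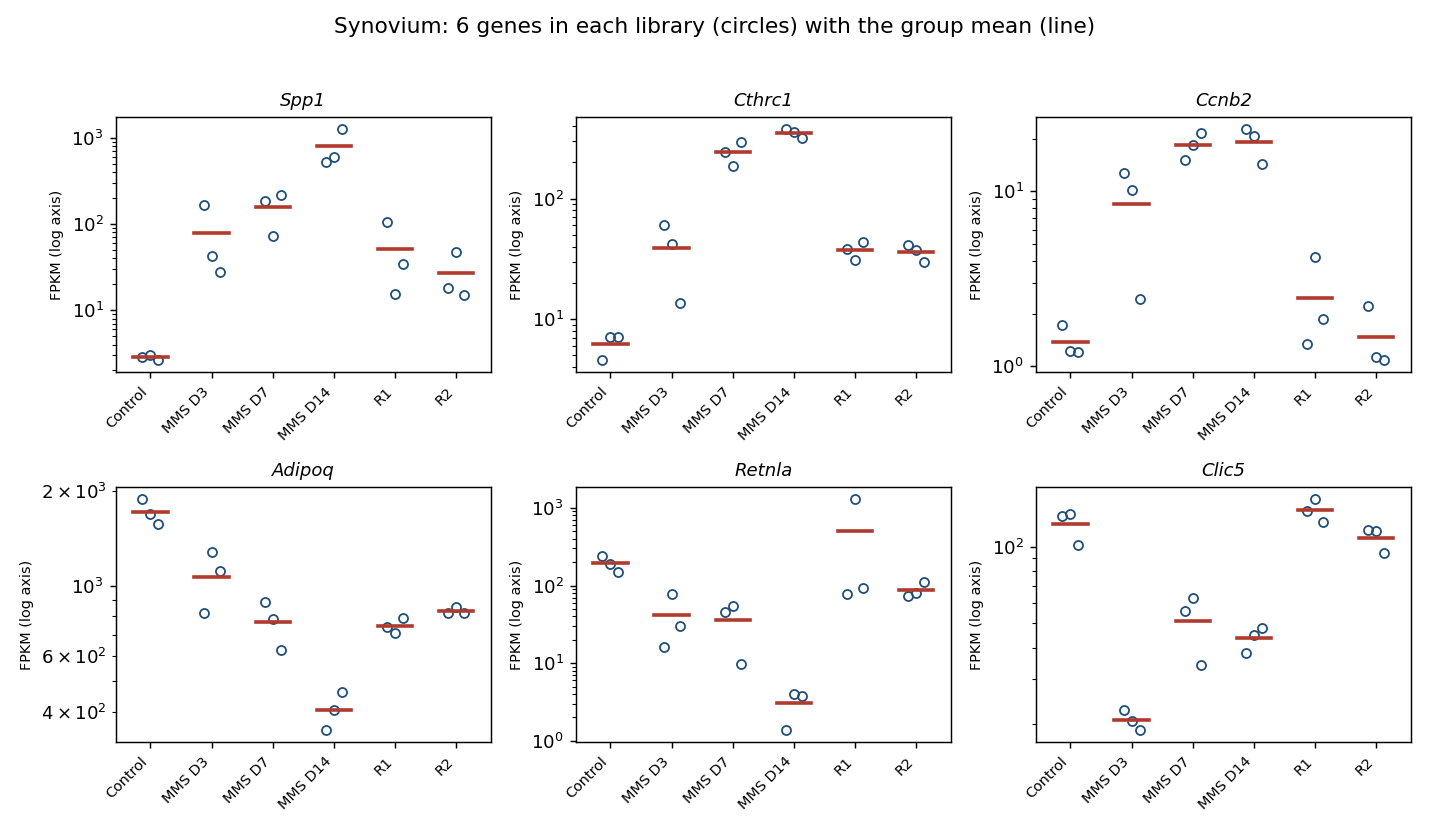
Deposited FPKM (log axis) of 6 synovium genes by group, where each circle is 1 library and each line is the group mean. Spp1 averaged 2.85 ± 0.221 in Control and 802 ± 416 in MMS D14, and Adipoq averaged 1715 ± 163 and 405 ± 56.6.

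R1 synovium was compared with Control. Mfap4, a microfibril-associated glycoprotein gene, rose from 6.24 ± 1.60 to 71.7 ± 17.7 (log2 change 3.32), and Mmp2 rose from 117 ± 15.7 to 541 ± 155 (log2 change 2.16). Spp1 rose from 2.85 ± 0.221 to 51.9 ± 47.5 (log2 change 3.37), and Cthrc1 rose from 6.24 ± 1.46 to 37.5 ± 6.16 (log2 change 2.42). Nnat, an imprinted gene for the membrane protein neuronatin, fell from 455 ± 225 to 86.9 ± 32.2 (log2 change -2.33), and Pck1 fell from 596 ± 91.2 to 169 ± 8.23 (log2 change -1.80). Fmod (2.55), Ccl8 (2.26), Thbs4 (2.12) and Tnc (2.12) were also among the largest rises. Hsd11b1 (-1.73), Arxes2 (-1.72), Ifi27l2a (-1.61), Adrb3 (-1.61), Ffar2 (-1.60) and Myl1 (-1.56) were among the largest falls. For these 16 genes adjusted p ran from 4.75e-06 to 0.0131. Without R1 replicate 1 the call for Adrb3 ended (adjusted p = 0.0520, 0.000268 to 0.0520 over its alternatives). Without Control replicate 2, where muscle genes were high, the call for Myl1 ended (adjusted p = 0.0703, 0.00129 to 0.0703 over its alternatives). limma called 720 of 1178 genes, 187 higher and 533 lower, or 245 and 419 after centring. In the adipocyte list 16 of 17 members fell (median log2 change -1.03, camera adjusted p = 0.00117, adjusted p = 0.517 with an estimated correlation), with Adipoq at 747 ± 43.3 against 1715 ± 163. In the fibrillar collagen and fibrosis list 16 of 20 members rose (median log2 change 0.92, camera adjusted p = 3.55e-10, adjusted p = 0.131 with an estimated correlation), with Col3a1 at 2072 ± 207 against 1025 ± 65.1. Within the matrix protease and inhibitor list 8 of 12 members rose (median log2 change 0.89, camera adjusted p = 5.67e-05, adjusted p = 0.0213 with an estimated correlation), and in the Wnt signalling list 3 of 5 members rose (median log2 change 1.07, camera adjusted p = 0.00174, adjusted p = 0.131 with an estimated correlation). None of the 10 cell cycle genes was called by limma, with 0 at an unadjusted p under 0.05, and the list's median log2 change was 0.42 (camera adjusted p = 0.0576). Retnla was 1319 in R1 replicate 2 and 78.7 and 93.6 in the other two.

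In R2 synovium, Mfap4 rose from 6.24 ± 1.60 to 67.4 ± 30.9 (log2 change 3.14) and Angptl1, a secreted angiopoietin-like protein gene, rose from 14.1 ± 0.0981 to 70.2 ± 8.32 (log2 change 2.23). Mmp3, which encodes stromelysin, rose from 6.58 ± 1.99 to 30.5 ± 10.1 (log2 change 2.03), and Spp1 rose from 2.85 ± 0.221 to 26.9 ± 18 (log2 change 2.67). Hsd11b1, the enzyme that regenerates active glucocorticoid, fell from 39.0 ± 5.65 to 10.6 ± 1.17 (log2 change -1.78), and Timp4 fell from 60.2 ± 18.2 to 18.9 ± 3.45 (log2 change -1.59). Cthrc1 (2.37), Fmod (2.25), Mmp2 (2.16) and Mfap2 (2.04) were the other largest rises. Adrb3 (-1.76), Arxes2 (-1.74), H2-Q10 (-1.58), Ifi27l2a (-1.52), Myl1 (-1.48) and Tshr (-1.46) were the other largest falls. Adjusted p over these 16 genes was 4.8e-06 to 0.0140, and Myl1 was no longer called without Control replicate 2 (adjusted p = 0.0956, 0.00267 to 0.0956 over its alternatives). H2-Q10 has close copies among the class I genes. The comparison called 716 of 1178 genes, 185 higher and 531 lower, or 252 and 365 after centring. Within the fibrillar collagen and fibrosis list 15 of 20 members rose (16 adjusted over the list alone) (median log2 change 1.01, camera adjusted p = 9.04e-11, adjusted p = 0.105 with an estimated correlation), with Aspn, which encodes asporin, at 179.6 ± 13.6 against 55.6 ± 3.23. In the adipocyte list 15 of 17 members fell (16 adjusted over the list alone) (median log2 change -1.05, camera adjusted p = 0.000624, adjusted p = 0.616 with an estimated correlation), with Pparg, the transcription factor of fat cell differentiation, at 53.5 ± 8.17 against 122 ± 20.2. In the matrix protease and inhibitor list 6 of 12 members rose (median log2 change 0.71, camera adjusted p = 6.92e-05, adjusted p = 0.0229 with an estimated correlation), and in the Wnt signalling list 3 of 5 members rose (median log2 change 1.27, camera adjusted p = 0.000624, adjusted p = 0.105 with an estimated correlation). All 5 interferon response genes fell, but camera did not call the list (adjusted p = 0.224). No cell cycle gene was called by limma, with 0 at an unadjusted p under 0.05, and the list's median log2 change was 0.05 (camera adjusted p = 0.224). A direct comparison of R2 with R1, added after the values were seen, called 0 genes by limma, with 52 genes at an unadjusted p under 0.05. Without the 5 libraries that stand apart it called 14.

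R1 and R2 synovium were each also compared with MMS D14, which asks how far these groups stood from the MMS D14 values. Spp1 fell from 802 ± 416 to 51.9 ± 47.5 (log2 change -4.22) in R1, and to 26.9 ± 18 in R2 (-4.92). Tnc fell from 154 ± 45.8 to 13.5 ± 2.68 (log2 change -3.39) in R1 and to 9.10 ± 1.76 in R2 (-3.91), and Cthrc1 fell from 352 ± 31.3 to 37.5 ± 6.16 (log2 change -3.20) in R1 and to 36.1 ± 5.79 in R2 (-3.26). Retnla rose from 3.04 ± 1.45 to 87.9 ± 19.1 (log2 change 4.51) in R2, and to 497 ± 712 in R1 (5.81). The larger R1 value rests on replicate 2, at 1319 against 78.7 and 93.6 in replicates 1 and 3. Adrb3 rose by a log2 change of 3.01 in R1 and 2.86 in R2, and Cyp2e1 by 2.63 and 2.77. In R1 the rule also named Dbp (2.86) and Cox8b (2.85) as higher, and Hist1h2ap (-2.59) and Fmod (-2.56) as lower. In R2 it named Myoc (2.80) and Tmem45b (2.52) as higher, and Hist1h2ap (-3.54) and Nt5dc2 (-3.28) as lower. Adjusted p ran from 2.86e-06 to 0.00504 in R1 and from 1.99e-07 to 0.000442 in R2. limma called 1049 genes in R1, 745 higher and 304 lower (474 and 331 after centring). In R2 it called 1042, 742 higher and 300 lower (518 and 326 after centring).

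All 10 cell cycle genes were lower than in MMS D14 in R1 (median log2 change -2.17, camera adjusted p = 1.13e-06, adjusted p = 0.221 with an estimated correlation) and in R2 (median log2 change -2.58, camera adjusted p = 2.58e-07, adjusted p = 0.217 with an estimated correlation). Birc5, the mitotic survivin gene, fell from 25.3 ± 10.8 to 1.93 ± 0.925 (log2 change -3.14) in R2. In the fibrillar collagen and fibrosis list 19 of 20 members fell in R1 (median log2 change -1.58, camera adjusted p = 1.08e-11, adjusted p = 0.127 with an estimated correlation) and 19 of 20 members fell in R2 (median log2 change -1.38, camera adjusted p = 2.00e-11, adjusted p = 0.135 with an estimated correlation). In the adipocyte list 16 of 17 members rose in R1 (median log2 change 1.29, camera adjusted p = 0.00835, adjusted p = 0.590 with an estimated correlation) and 17 of 17 members rose in R2 (median log2 change 1.18, camera adjusted p = 0.00920, adjusted p = 0.613 with an estimated correlation), with Dgat2 at 276 ± 31.0 against 75.4 ± 23.2 in R2. Within the matrix protease and inhibitor list 2 of 12 members rose and 8 fell in R1 (median log2 change -0.83, camera adjusted p = 0.00245, adjusted p = 0.113 with an estimated correlation) and 1 of 12 members rose and 8 fell in R2 (median log2 change -0.95, camera adjusted p = 0.00157, adjusted p = 0.0928 with an estimated correlation). Timp3 was among the members that rose in R2, from 36.3 ± 3.11 to 142 ± 77.6 (log2 change 1.81). In the Wnt signalling list 1 of 5 members rose and 4 fell in R1 (median log2 change -1.59, camera adjusted p = 0.0137, adjusted p = 0.221 with an estimated correlation) and 1 of 5 members rose and 4 fell in R2 (median log2 change -1.56, camera adjusted p = 0.0204, adjusted p = 0.217 with an estimated correlation), where Sfrp4 rose from 52.6 ± 4.8 to 152 ± 28.1 (log2 change 1.5) in R2. All 5 synovial lining fibroblast genes rose in both groups, but camera called the list in neither (adjusted p = 0.0868 and 0.0913). In the antigen presentation and complement list 7 of 8 members rose in R1 and 8 of 8 members rose in R2, without a camera call (adjusted p = 0.0957 and 0.209), and H2-Eb1, a class II antigen gene, rose from 80.9 ± 6.34 to 205 ± 45.3 (log2 change 1.31) in R1.

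In cartilage MMS D3 was first compared with Control. Stfa2, a stefin gene of myeloid cells (chromosome 16, 36403992 to 36408457, GRCm38), rose from 2.69 ± 1.08 to 48.1 ± 3.73 (log2 change 3.76), and Serpina3n, an acute-phase protease inhibitor gene, rose from 28.2 ± 9.85 to 366 ± 138 (log2 change 3.64). Chil1, a chitinase-like glycoprotein gene, rose from 188 ± 42.0 to 1829 ± 573 (log2 change 3.25). Bglap2 and its near-identical copy Bglap, which encode osteocalcin, fell from 1304 ± 48.4 to 237 ± 71.6 (log2 change -2.49) and from 2546 ± 28.4 to 626 ± 244 (log2 change -2.08). Isg15, an interferon-induced gene, fell from 43.6 ± 5.49 to 13.0 ± 0.212 (log2 change -1.66). Other large rises were in BC100530 (3.13), Stfa1 (2.28), Stfa2l1 (1.96), Wfdc17 (1.84) and Ifitm1 (1.49). Other large falls were in Cfd (-2.70), Ifi27l2a (-2.09), Car3 (-1.72), Apol11b (-1.71) and Myl4 (-1.66). These 16 genes had adjusted p of 5.45e-06 to 0.0126, and the Stfa genes with BC100530 are near-identical copies whose shared reads were assigned in a way that is not stated. All 4 skeletal muscle genes measured were lower than in Control in each of the 6 other cartilage groups, at an unadjusted p under 0.05, so muscle transcript in Control accompanies every cartilage comparison with it. Control replicate 2 held more fat and muscle transcript, with Cfd at 302 against 93.7 in replicate 1. Without it, Cfd and Car3 were not called, and their log2 changes were -1.86 and -1.12, against -2.70 and -1.72 with all samples. Cfd was also lost without MMS D3 replicate 1 (log2 change -2.42) and Car3 without MMS D3 replicate 2 (log2 change -1.37). limma called 383 of 1606 genes, 207 higher and 176 lower, or 163 and 205 after centring. The number was 206 without Control replicate 1, 126 without Control replicate 2, 168 without MMS D3 replicate 1 and 150 without MMS D3 replicate 2. In the osteoblast and osteocyte list 5 of 12 members fell (6 adjusted over the list alone) (median log2 change -0.51, camera adjusted p = 0.000538, adjusted p = 0.847 with an estimated correlation). In the T cell, B cell and NK cell list 5 of 8 members fell (7 adjusted over the list alone) (median log2 change -0.58, camera adjusted p = 0.000538, adjusted p = 0.847 with an estimated correlation), with Vpreb3, a gene of developing B cells, at 50.2 ± 0.460 against 119.8 ± 6.47. The chondrocyte matrix list was not called (median log2 change 0.12, camera adjusted p = 0.949, adjusted p = 0.967 with an estimated correlation), and Acan, which encodes aggrecan, rose from 203 ± 40.4 to 421 ± 29.0 (log2 change 1.06). The call for Acan (adjusted p = 0.00959, 0.00127 to 0.0978 over its alternatives) ended without Control replicate 2 (0.0978) or MMS D3 replicate 1 (0.0640).

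MMS D7 cartilage was compared with Control next. Mmp13, the main collagenase gene of cartilage, rose from 108 ± 9.82 to 471 ± 79.1 (log2 change 2.11). Chil1 rose from 188 ± 42.0 to 2165 ± 199 (log2 change 3.53), and Wisp2, a secreted matricellular protein gene, rose from 6.54 ± 0.495 to 34.5 ± 4.72 (log2 change 2.23). Spib and Fam129c, both expressed in B cells, fell from 92.0 ± 4.34 to 25.7 ± 0.891 (log2 change -1.80) and from 36.1 ± 2.16 to 9.34 ± 1.87 (log2 change -1.86). Other rises were in Stfa2 (2.94), Serpina3n (2.72), Stfa1 (2.08), BC100530 (2.05) and Col3a1 (1.87). Other falls were in Myl4 (-2.00), Serpina1b (-1.85), Ly6d (-1.84), Serpina1e (-1.83), Serpina1a (-1.78) and Cfd (-1.77), and the Serpina1 genes are near-identical copies. Adjusted p ran from 4.93e-06 to 0.0466. The call for Col3a1 (0.00177 to 0.149 over its alternatives) ended without Control replicate 1 (adjusted p = 0.149), MMS D7 replicate 1 (0.0979) or MMS D7 replicate 2 (0.0790). The call for Cfd (0.0129 to 0.341 over its alternatives) ended without Control replicate 2 (adjusted p = 0.341), MMS D7 replicate 1 (0.187) or MMS D7 replicate 2 (0.110), and with centring (0.0528). The comparison called 359 of 1606 genes, 109 higher and 250 lower, or 148 and 184 after centring. It called 218 without Control replicate 1, 197 without Control replicate 2 and 227 without MMS D7 replicate 1. In the T cell, B cell and NK cell list 6 of 8 members fell (7 adjusted over the list alone) (median log2 change -1.45, camera adjusted p = 6.66e-05, adjusted p = 0.371 with an estimated correlation), and Ms4a1, which encodes the B cell antigen CD20 (chromosome 19, 11249675 to 11266241), fell from 40.1 ± 6.18 to 11.4 ± 0.672 (log2 change -1.73). In the matrix protease and inhibitor list 5 of 8 members rose (median log2 change 0.72, camera adjusted p = 0.00160, adjusted p = 0.287 with an estimated correlation). In the chondrocyte matrix list 4 of 17 members fell, without a camera call (median log2 change -0.30, camera adjusted p = 0.10, adjusted p = 0.851 with an estimated correlation), and Cilp2, a cartilage intermediate layer protein gene (chromosome 8, 69880369 to 69887687), fell from 169 ± 25.1 to 63.0 ± 22.8 (log2 change -1.45).

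In MMS D14 cartilage, Cilp2 fell from 169 ± 25.1 to 13.3 ± 2.01 (log2 change -3.57), and Ucma, a matrix protein gene of the upper cartilage zone, fell from 96.8 ± 0.863 to 17.4 ± 2.31 (log2 change -2.41). Cytl1, a cytokine-like gene of chondrocytes, fell from 7199 ± 1068 to 1026 ± 36.4 (log2 change -2.80), and Chad, which encodes chondroadherin, fell from 8691 ± 1778 to 2153 ± 93.7 (log2 change -2.00). Col3a1, a fibrillar collagen gene of soft connective tissue, rose from 57.8 ± 17.3 to 537 ± 151 (log2 change 3.20), and Postn rose from 10.8 ± 0.544 to 61.1 ± 14.7 (log2 change 2.38). Other rises were in Stfa2 (4.03), BC100530 (3.84), Stfa1 (3.50), Cthrc1 (2.52), Chil1 (2.52) and Wisp2 (2.36). Other falls were in Serpina1e (-3.65), Serpina1b (-2.96), Serpina1d (-2.89), Sfrp5 (-2.82) and Serpina1a (-2.36). The named genes had adjusted p of 1.80e-06 to 0.00131. limma called 859 of 1606 genes, 410 higher and 449 lower (486 and 399 after centring), with 502 without Control replicate 1 and 502 without MMS D14 replicate 2. In the chondrocyte matrix list 13 of 17 members fell (14 adjusted over the list alone) (median log2 change -1.09, camera adjusted p = 5.48e-05, adjusted p = 0.638 with an estimated correlation). Within the fibrillar collagen and fibrosis list 6 of 8 members rose and 1 fell (median log2 change 2.45, camera adjusted p = 0.0367, adjusted p = 0.638 with an estimated correlation). Within the matrix protease and inhibitor list 6 of 8 members rose (median log2 change 1.46, camera adjusted p = 0.00346, adjusted p = 0.413 with an estimated correlation), with Mmp13 at 458 ± 28.2 against 108 ± 9.82. In the T cell, B cell and NK cell list 0 of 8 members rose and 7 fell (1 and 7 adjusted over the list alone) (median log2 change -1.61, camera adjusted p = 0.00346, adjusted p = 0.638 with an estimated correlation), with Cd79b, a B cell receptor subunit gene, at 47.6 ± 6.46 against 156 ± 11. In the neutrophil list 3 of 13 members rose (2 adjusted over the list alone) (median log2 change 0.45, camera adjusted p = 0.0436, adjusted p = 0.674 with an estimated correlation), and Ctsg, a granule protease gene, rose from 155 ± 9.55 to 364 ± 14.1 (log2 change 1.23). The neutrophil call (adjusted p 0.0103 to 0.165 over its alternatives) ended without Control replicate 1 (0.0600), Control replicate 2 (0.0555) or MMS D14 replicate 2 (0.165), and with centring (0.0572). Panx3, a channel gene of hypertrophic chondrocytes, rose from 3.25 ± 0.516 to 21.4 ± 2.45 (log2 change 2.40), while Ihh, the Indian hedgehog gene, fell from 15.9 ± 0.735 to 5.79 ± 0.742 (log2 change -1.32).

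In MMS D28 cartilage, all 17 measured chondrocyte matrix genes fell (median log2 change -1.21, camera adjusted p = 0.00180, adjusted p = 0.573 with an estimated correlation). All 13 measured neutrophil genes rose (median log2 change 0.88, camera adjusted p = 0.00180, adjusted p = 0.573 with an estimated correlation). Cilp2 fell from 169 ± 25.1 to 21.7 ± 4.26 (log2 change -2.91), and Wif1, a secreted Wnt inhibitor gene, fell from 394 ± 31.2 to 132 ± 22.1 (log2 change -1.57). Ctsg rose from 155 ± 9.55 to 463 ± 71.9 (log2 change 1.56), and Prtn3, which encodes neutrophil proteinase 3, rose from 402 ± 5.37 to 1051 ± 219 (log2 change 1.37). Ms4a1 fell from 40.1 ± 6.18 to 7.09 ± 2.86 (log2 change -2.38), and Tnfrsf13c, the receptor gene for the B cell survival factor BAFF, fell from 24.4 ± 2.84 to 4.38 ± 1.03 (log2 change -2.25). The rule named Stfa2 (3.60), Stfa1 (2.90), BC100530 (2.87), Serpina3n (2.40), Ifitm1 (2.39), Wfdc17 (2.20), Asprv1 (2.03) and Stfa2l1 (1.99) as higher. It named Slurp1 (-3.06), Serpina1d (-2.47), Spib (-2.33), Serpina1a (-2.24) and Gas1 (-2.16) as lower, with adjusted p of 2.23e-06 to 0.000270 over its 16 genes. The count was 1563 of 1606 genes, 686 higher and 877 lower. Every gene of the table differed at least 1.49-fold between the means of MMS D28 and Control. Apart from the directions, the count is therefore largely fixed by the selection. In the osteoblast and osteocyte list 11 of 12 members fell (median log2 change -0.91, camera adjusted p = 0.0256, adjusted p = 0.611 with an estimated correlation), with Sost, the sclerostin gene of osteocytes (chromosome 11, 101962458 to 101967015), at 30.9 ± 6.41 against 95.4 ± 1.73. In the T cell, B cell and NK cell list 1 of 8 members rose and 7 fell (median log2 change -1.90, camera adjusted p = 0.0256, adjusted p = 0.573 with an estimated correlation). In the Wnt signalling list 1 of 10 members rose and 9 fell (median log2 change -1.03, camera adjusted p = 0.0426, adjusted p = 0.573 with an estimated correlation), a call that ended without MMS D28 replicate 1 (adjusted p = 0.0571, 0.0337 to 0.0571 over its alternatives) or replicate 2 (0.0510). In the inflammatory cytokine and chemokine list 4 of 5 members rose (median log2 change 0.75, camera adjusted p = 0.0426, adjusted p = 0.573 with an estimated correlation), with Osm, which encodes oncostatin M, at 10.7 ± 0.389 against 4.97 ± 0.0636. In the matrix protease and inhibitor list 6 of 8 members rose (median log2 change 0.77, camera adjusted p = 0.0337, adjusted p = 0.573 with an estimated correlation). The cytokine call ended without MMS D28 replicate 2 (adjusted p = 0.111, 0.0266 to 0.111 over its alternatives), as did the protease call (adjusted p = 0.0740, 0.0194 to 0.0740). The replicates differed in soft tissue transcript, with Col3a1 at 94.2 in replicate 1 and 335 in replicate 2.

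**Figure D3:**
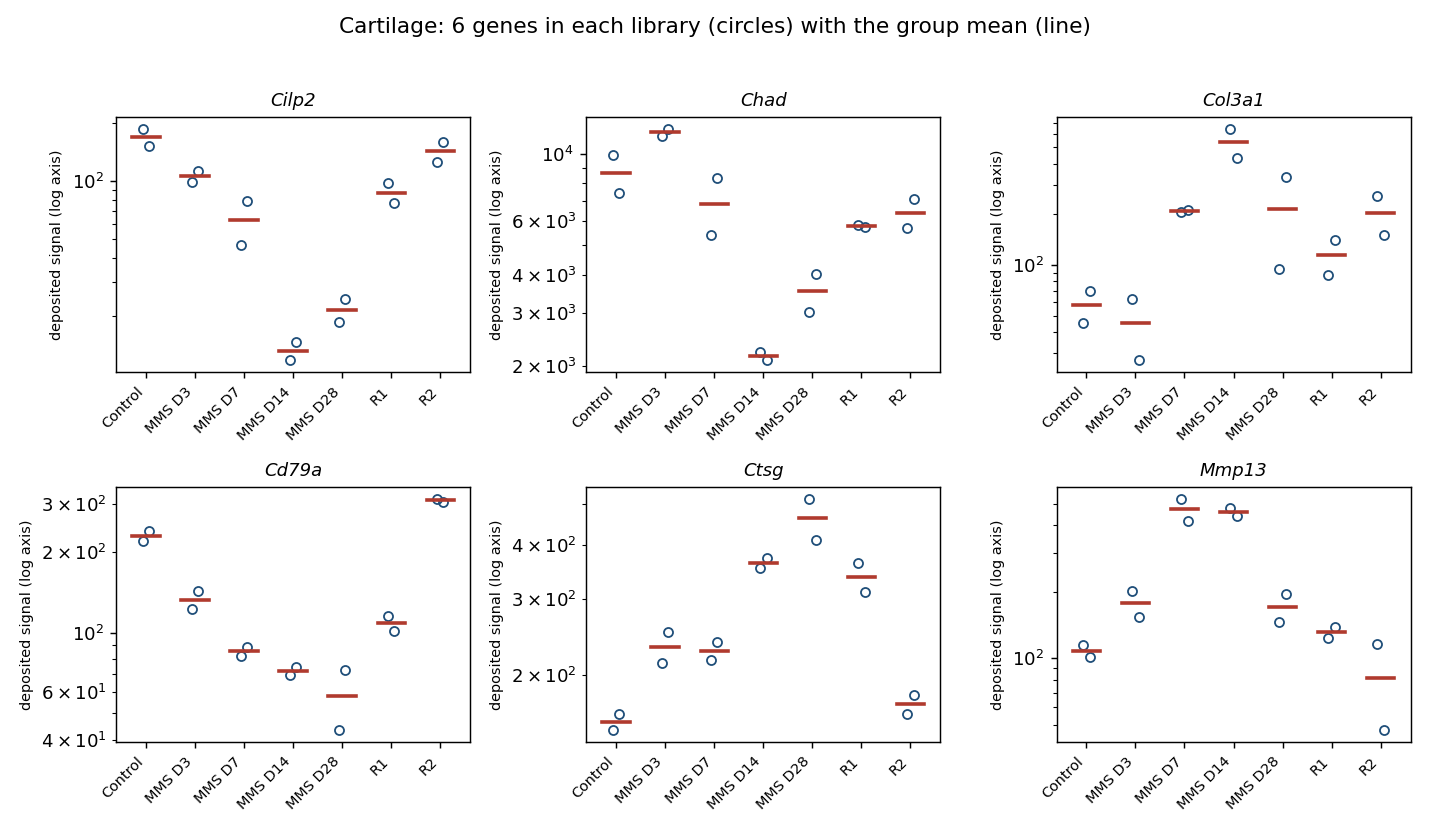
Deposited signal (log axis, unit not stated) of 6 cartilage genes by group, where each circle is 1 library and each line is the group mean. Cilp2 averaged 169 ± 25.1 in Control, 13.3 ± 2.01 in MMS D14 and 87.2 ± 14.7 in R1, and Cd79a averaged 229 ± 14.5, 72.0 ± 3.28 and 108 ± 9.85.

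R1 cartilage against Control showed all 13 neutrophil genes higher (median log2 change 0.81, camera adjusted p = 0.000678, adjusted p = 0.512 with an estimated correlation), with Cxcr2, a neutrophil chemokine receptor gene, at 78.8 ± 0.318 against 37.9 ± 1.73. Ifitm1, an interferon-induced membrane protein gene, rose from 35.8 ± 2.55 to 144 ± 26.1 (log2 change 1.96), and Il1r2, the interleukin-1 decoy receptor gene, rose from 10.3 ± 1.11 to 28.9 ± 4.25 (log2 change 1.40). Sost fell from 95.4 ± 1.73 to 34.0 ± 2.82 (log2 change -1.46), and Mepe, a matrix phosphoglycoprotein gene of osteocytes, fell from 116 ± 13.0 to 43.2 ± 6.18 (log2 change -1.41). Cfd, which encodes the complement factor adipsin of fat cells, fell from 198 ± 147 to 13.8 ± 6.20 (log2 change -3.58). Other rises were in Stfa1 (1.96), Wfdc17 (1.95), Stfa2 (1.90), Ms4a6d (1.56), Lrg1 (1.41) and Slfn4 (1.41). Other falls were in Serpina1d (-2.20), Slurp1 (-2.02), Serpina1a (-2.02), Car3 (-1.81), Serpina1b (-1.71), Serpina1e (-1.69) and Scd1 (-1.68). Adjusted p of the 16 genes under the rule ran from 3.54e-05 to 0.00732, and Scd1 was lost without Control replicate 2 (adjusted p = 0.0631, 0.00351 to 0.0631 over its alternatives). limma called 1112 of 1606 genes, 578 higher and 534 lower, or 624 and 308 after centring. It called 536 without Control replicate 1, 636 without R1 replicate 1 and 564 without R1 replicate 2. In the osteoblast and osteocyte list 7 of 12 members fell (6 adjusted over the list alone) (median log2 change -0.64, camera adjusted p = 0.0188, adjusted p = 0.553 with an estimated correlation), a call that ended without R1 replicate 2 (adjusted p = 0.0515, 0.00196 to 0.0515 over its alternatives). In the T cell, B cell and NK cell list 1 of 8 members rose and 6 fell (median log2 change -1.04, camera adjusted p = 0.0280, adjusted p = 0.512 with an estimated correlation), a call that ended without Control replicate 2 (0.0598, 0.0191 to 0.0598 over its alternatives). In the chondrocyte matrix list 4 of 17 members fell (1 adjusted over the list alone) (median log2 change -0.50, camera adjusted p = 0.0280, adjusted p = 0.553 with an estimated correlation), a call that ended without Control replicate 1 (0.142, 0.00887 to 0.142 over its alternatives) or R1 replicate 2 (0.0751). In the Wnt signalling list 1 of 10 members rose and 8 fell (median log2 change -0.56, camera adjusted p = 0.0280, adjusted p = 0.512 with an estimated correlation), and Dkk1, a secreted Wnt inhibitor gene, fell from 13.1 ± 0.863 to 6.06 ± 0.354 (log2 change -1.0).

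R2 cartilage was compared with Control as well. Jchain, the joining chain gene of secreted antibodies (chromosome 5, 88519809 to 88527891), rose from 27.5 ± 0.721 to 66.0 ± 3.66 (log2 change 1.23). Sost fell from 95.4 ± 1.73 to 49.2 ± 0.219 (log2 change -0.94), Mepe fell from 116 ± 13.0 to 52.6 ± 12.8 (log2 change -1.14), and the small heat shock protein gene Hspb1 fell from 35.3 ± 1.93 to 20.0 ± 0.502 (log2 change -0.79). Serpina1d (-1.75) and Serpina1e (-1.31) were the other two genes under the rule, with adjusted p of 0.0326 to 0.0464 over the 6. limma called 12 genes in all, 1 higher and 11 lower, with 251 genes at an unadjusted p under 0.05. The calls of the 6 named genes ended under several alternatives. Over the alternatives, log2 changes were 1.18 to 1.29 for Jchain, -0.96 to -0.89 for Sost and -0.84 to -0.73 for Hspb1. They spread more for Mepe (-1.39 to -0.90), Serpina1d (-2.28 to -1.23) and Serpina1e (-1.72 to -0.89). Of the 6 genes, 1 was called without Control replicate 1 (adjusted p 0.0358 to 0.240) and 2 without Control replicate 2 (0.00886 to 0.167). Without R2 replicate 1 it was 1 (0.0291 to 0.155), and without R2 replicate 2 none was called (0.0698 to 0.132). None was called with the replicate number as a block (0.0511 to 0.0691) or with only the 2 groups compared (0.0572 to 0.161). With centring 5 were called (0.0376 to 0.0518), and with a pseudocount of 0.10 it was 5 (0.0333 to 0.0536). The count of called genes was 3 without Control replicate 2 and 0 without R2 replicate 2, where 168 genes had an unadjusted limma p under 0.05. Camera called no list here, and the smallest adjusted p was 0.0520, shared by the fibrillar collagen and fibrosis list (median log2 change 0.66) and the Wnt signalling list (-0.29). No gene of the T cell, B cell and NK cell list was called by limma, with 1 at an unadjusted p under 0.05, and Cd79a was 311 ± 5.68 against 229 ± 14.5 in Control (adjusted p = 0.315).

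R1 and R2 cartilage were then compared with MMS D14. Cilp2 rose from 13.3 ± 2.01 to 87.2 ± 14.7 (log2 change 2.62) in R1 and to 142 ± 23.3 in R2 (3.33). Sfrp5, a secreted Wnt antagonist gene, rose from 4.19 ± 0.368 to 34.5 ± 4.67 (log2 change 2.77) in R2 and by 2.08 in R1. Postn fell from 61.1 ± 14.7 to 7.67 ± 0.771 (log2 change -2.82) in R1, and Stfa2 fell from 58.2 ± 6.35 to 2.66 ± 1.51 (log2 change -4.07) in R2. R1 also had Cytl1 (2.12), Serpina1e (1.96) and Grem1 (1.80) higher, and BC100530 (-2.76), Cthrc1 (-2.63), Chil1 (-2.43) and Cfd (-2.33) lower. R2 also had Serpina1b (2.56), Spib (2.50) and Fam129c (2.44) higher, and BC100530 (-3.94), Mt3 (-3.07), Chil1 (-2.95) and Stfa1 (-2.91) lower. Adjusted p ran from 0.000179 to 0.0161 in R1 and from 1.81e-06 to 0.000244 in R2. The call for Cfd in R1 (0.000616 to 0.128 over its alternatives) ended without MMS D14 replicate 1 (adjusted p = 0.0926), MMS D14 replicate 2 (0.0562) or R1 replicate 1 (0.128). R1 had 290 genes called, 133 higher and 157 lower (162 and 149 after centring). The total was 125 and 170 without MMS D14 replicates 1 and 2, and 145 and 117 without R1 replicates 1 and 2. R2 had 573 genes called, 318 higher and 255 lower, or 345 without MMS D14 replicate 2.

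In the chondrocyte matrix list 9 of 17 members rose (10 adjusted over the list alone) in R1 over MMS D14 (median log2 change 0.71, camera adjusted p = 0.000566, adjusted p = 0.605 with an estimated correlation), and 11 of 17 members rose in R2 (median log2 change 1.12, camera adjusted p = 1.22e-05, adjusted p = 0.685 with an estimated correlation). Chad rose from 2153 ± 93.7 to 5772 ± 58.8 (log2 change 1.42) in R1. In the T cell, B cell and NK cell list 7 of 8 members rose in R2 (median log2 change 1.89, camera adjusted p = 7.64e-05, adjusted p = 0.425 with an estimated correlation), with Cd79a at 311 ± 5.68 against 72.0 ± 3.28, and 1 of 8 members rose (5 adjusted over the list alone) in R1 (median log2 change 0.50, camera adjusted p = 0.0433, adjusted p = 0.605 with an estimated correlation). The R1 call for that list ended without MMS D14 replicate 1 (adjusted p = 0.0832, 0.0214 to 0.0832 over its alternatives) or R1 replicate 1 (0.0570). In the fibrillar collagen and fibrosis list 5 of 8 members fell (7 adjusted over the list alone) in R1 (median log2 change -1.90, camera adjusted p = 0.000138, adjusted p = 0.605 with an estimated correlation), with Acta2, a contractile actin gene, at 4.33 ± 0.177 against 14.4 ± 0.177. Within the matrix protease and inhibitor list 0 of 8 members rose and 5 fell (1 and 5 adjusted over the list alone) in R1 (median log2 change -0.76, camera adjusted p = 0.0303, adjusted p = 0.605 with an estimated correlation) and 5 of 8 members fell in R2 (median log2 change -1.10, camera adjusted p = 0.0124, adjusted p = 0.425 with an estimated correlation), where Mmp13 fell from 458 ± 28.2 to 81.8 ± 48.8 (log2 change -2.61). Camera also called 3 further lists in R1, each near the threshold. The osteoblast and osteocyte list was lower (camera adjusted p = 0.0447, 0.768 with an estimated correlation) and was lost without MMS D14 replicate 2 (0.255) or R1 replicate 2 (0.306). The neutrophil list was higher with no single member called by limma and 5 of 13 at an unadjusted p under 0.05 (camera adjusted p = 0.0433, 0.768 with an estimated correlation). It was lost without MMS D14 replicate 1 (0.371) or R1 replicate 1 (0.109), and with centring (0.0699). The antigen presentation and complement list was lower (camera adjusted p = 0.0433, 0.605 with an estimated correlation) and was lost without MMS D14 replicate 2 (0.0686) or R1 replicate 2 (0.0763). Over their alternatives, adjusted p of these 3 lists ran over 0.00938 to 0.306, 0.00856 to 0.371 and 0.0408 to 0.0763, in the order named.

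A direct comparison of R2 with R1 in cartilage was added after the values were seen, and so were the genes named for it. Cd79a, a B cell receptor subunit gene, was 311 ± 5.68 against 108 ± 9.85 in R1 (log2 change 1.52), and Ms4a1 was 45 ± 3.46 against 15.2 ± 1.61 (1.5). Fcmr, the receptor gene for IgM, rose from 17.2 ± 1.61 to 60.4 ± 5.85 (log2 change 1.75). Ifitm1 was 43.9 ± 4.13 against 144 ± 26.1 (-1.68), and Lrg1, a glycoprotein gene of neutrophil granules, was 133 ± 17.5 against 311 ± 7.71 (-1.22). Adjusted p was 0.000439 for Cd79a, 0.000791 for Ms4a1, 0.000305 for Fcmr, 0.000208 for Ifitm1 and 0.00155 for Lrg1. limma called 571 genes, 212 higher and 359 lower in R2. In the neutrophil list 8 of 13 genes fell, and in the T cell, B cell and NK cell list 6 of 8 rose and 1 fell. The count was 178 without R1 replicate 1 (103 higher and 75 lower), 140 without R1 replicate 2 (80 and 60) and 138 without R2 replicate 1 (85 and 53). With a required absolute log2 change of at least 1, 41 were higher and 19 lower, so the excess of lower genes was not stable.

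The tissues were compared through the 240 genes present in both tables. Across genes, the log2 changes against Control in synovium and cartilage had a Pearson correlation of 0.23 in MMS D3 (Spearman 0.24), 0.44 in MMS D7 (0.34) and 0.38 in MMS D14 (0.27). It was 0.08 in R1 (0.03) and 0.40 in R2 (0.31). Leaving out single libraries moved the Pearson value over 0.00314 to 0.133 in R1 and 0.260 to 0.470 in R2. Genes are not independent replicates, so no p-value is given, and the groups' correlations were not tested against each other. In MMS D14, 54 genes were higher in both tissues, 93 lower in both, and 40 and 53 went opposite ways, whether or not they passed a test. Cthrc1 rose in MMS D14 in both tissues, from 6.24 ± 1.46 to 352 ± 31.3 (log2 change 5.63) FPKM in synovium and from 8.99 ± 1.09 to 56.2 ± 4.18 (log2 change 2.52) signal in cartilage. Wisp2 likewise rose from 17.4 ± 4.12 to 238 ± 13.8 (log2 change 3.73) FPKM in synovium and from 6.54 ± 0.495 to 37.8 ± 1.44 (log2 change 2.36) signal in cartilage. The units of the tables differ or are unstated, so levels cannot be set against each other across tissues.

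The synovium libraries also differed in a way the groups do not describe. In 5 of the 6 groups, all but R1, replicate 3 had low values of the predicted genes Gm2023, at most 3.36 against at least 12.6 in the 13 other libraries, and Gm6958, at most 2.30 against at least 5.12. These are the libraries that stand apart, found after the values were seen. With the set as a term, limma called 295 of 1176 other genes between the set and the rest (25.1%). Of the calls against Control, all 659 genes called in MMS D3, 1010 in MMS D7, 1142 in MMS D14 and 716 in R2 were called again in the same direction with that term, and 710 of 720 in R1. The term also raised the counts, to 749 in MMS D3, 1038 in MMS D7, 1150 in MMS D14, 764 in R1 and 793 in R2. Circadian clock genes differed between replicate 3 and the others within Control, MMS D7 and R2. The median log2 difference of 6 clock genes was 1.41 in Control, 0.34 in MMS D3, -0.95 in MMS D7, 0.09 in MMS D14 and 2.38 in R2. For all genes the median absolute difference was 0.26, 0.32, 0.28, 0.29 and 0.30 in the same order. In MMS D3 and MMS D14 the clock genes thus did not stand clearly beyond it. Dbp, a clock gene named above for R1 against MMS D14, was 127 in Control replicate 3 against 18.4 and 15.6 in replicates 1 and 2. In R2 it was 207 in replicate 3 against 19.1 and 20.2. Its values were 78.4 to 122 in R1 and 8.97 to 16.6 in MMS D14, so it also differed between whole groups.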

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

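The tests of the fat share, the library shift, the cartilage share, the marrow cells, the library set and the time of day were chosen after the result was seen, and the splits of the samples were chosen before.

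Of 164 pairs of a named gene and a group, 54 had the gene in both tables, and 7 moved opposite ways in the tissues, with every sample of the group beyond every Control sample in both. In cartilage, with 2 samples per group, such separation held for 68.6% of all genes in MMS D3 and 58.5% in MMS D7. It held for 84.6% in MMS D14 and 91.7% in R1, so separation alone says little there. In each of the 7 the difference was not tested, since a test across tissues was planned only for raw counts. Rbp4 in MMS D3 had a log2 change of -2.10 in synovium and 0.49 in cartilage, where it was not called (adjusted p = 0.0854). Myoc in MMS D7 had -2.48 and 1.0, the cartilage value again not called (adjusted p = 0.111). Thbs4 had 4.44 in synovium and -1.45 in cartilage in MMS D14, and 2.12 and -1.18 in R1. In R1, Hsd11b1 had -1.73 and 0.80, Ffar2 had -1.60 and 0.64, and Il1r2 had -1.68 and 1.40. The Thbs4, Hsd11b1, Ffar2 and Il1r2 changes passed the test in both tissues.

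Adipocyte genes were lower in MMS D14 synovium, which raises the question of how much fat was in the tissue taken. A smaller share of fat as the whole cause would keep the ratio of these genes to Adipoq, if the fat taken had the same make-up in both groups. Instead 7 of 16 other adipocyte genes were lower relative to Adipoq, down to -1.39 for Pck1, and 1 was higher, Plin4 at 0.63. The rest did not pass, such as Fabp4 at 0.04 and Car3 at 0.02. All 16 ratios share the Adipoq values, so they are not independent. Within that limit, the ratios argue against a smaller share of fat of unchanged make-up as the whole cause. All 17 genes were still lower after median centring. That does not decide on a shift of whole libraries, since the median is taken over selected genes that nearly all differ between MMS D14 and Control. A smaller share of fat as part of the cause stays open, and expression within fat cells was not tested.

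Chondrocyte matrix genes were lower in cartilage of MMS D14 and MMS D28. The fit of the ratios to Col2a1 gave 16 other genes of the list a common spread. All of them share the Col2a1 values of 2 samples per group, so they are not independent. Those values were 906 and 638 in Control and 192 and 517 in MMS D28. In MMS D14, 5 of the 16 were lower relative to Col2a1, down to -2.87 for Cilp2. Within that limit, this argues against a smaller share of cartilage of unchanged make-up as the whole cause. In MMS D28 only 1 gene was lower relative to Col2a1, Cilp2 at -1.64. A smaller share of cartilage and lower expression cannot be told apart there. A single gene does not decide for the list, and the Col2a1 values of the MMS D28 samples lie far apart. More marrow cells of all kinds would raise B cell genes along with neutrophil genes, but the median log2 change of 6 B cell genes was -1.68 in MMS D14 and -1.96 in MMS D28. A smaller share of cartilage as part of the cause stays open in MMS D14, and expression within chondrocytes was not tested.

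The third libraries of Control, MMS D3, MMS D7, MMS D14 and R2 in synovium stood apart. Between this set and the other libraries 295 genes differed, against at most 216 for other choices of 1 library per group, drawn at random to make 99 with the real one, which is consistent with a shared library set. A shared time of day would shift the clock genes the same way in all 5 groups only if the other libraries also shared a time. All clock genes were lower in the third library in 1 group, MMS D7, and all were higher in Control. In replicates 1 and 2, however, Dbp was 18.4 and 15.6 in Control and 70.8 and 89.6 in MMS D7. The direction of the shift therefore cannot decide whether the third libraries shared a time of day. In the third libraries, Dbp was 127 in Control, 97.7 in MMS D3, 13.8 in MMS D7, 8.97 in MMS D14 and 207 in R2. Tef and Per3 followed the same order. Hlf and Nr1d2 were also highest in R2 and lower in MMS D7 and MMS D14 than in Control and MMS D3. These levels argue against 1 time of day shared by all 5, unless the groups themselves changed the clock genes, which was not tested. No sequencing batch or date is given in the labels, and no biological explanation was tested.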

How the results depend on the processing

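The term for the synovium library set, leaving that set out, centring in the gene list tests and the comparisons of R2 with R1 were chosen after seeing the data, and the other alternatives were planned. The filter on low values removed no gene, so dropping it says nothing about stability. No gene change or list call given in the text changed direction under any alternative. The balance of higher and lower calls did turn in cartilage. It turned with centring in MMS D3, MMS D14 and R1 against MMS D14, and with only the 2 groups compared in MMS D14, R1 and R1 against MMS D14. It also turned in R1 with the required log2 change of 1, and in R1 against MMS D14 without MMS D14 replicate 1. Between R2 and R1 it turned with the required log2 change of 1 and without R1 replicate 1, R1 replicate 2 or R2 replicate 1.

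Of 269 changes of single genes given in the text, 251 kept their direction and side of the threshold under every alternative run, and 18 ended at least once. Of 65 gene list calls, 52 held under every alternative except the estimated correlation, and 13 ended under another one. With the estimated correlation, the calls fell to 4 of 34 in synovium and 0 of 31 in cartilage, where camera gave 5 tests at an unadjusted p under 0.05. That alternative estimates the correlation among list members from the residuals, in place of the preset value. How many calls it ends is therefore not fixed by construction. The calls that ended with it rest on the preset correlation.

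A required absolute log2 change of at least 1 lowers each count by construction. In synovium it left 203 genes in MMS D3, 474 in MMS D7, 209 in R1 and 197 in R2 against Control, and 453 in R1 and 455 in R2 against MMS D14. In cartilage it left 64 genes in MMS D3, 111 in MMS D7, 211 in MMS D14, 288 in MMS D28, 103 in R1 and 5 in R2. Against MMS D14 it left 86 in R1 and 170 in R2, and between R2 and R1 it left 60.

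For cartilage R2 against Control, the replicate number as a block left 1 called gene, and the cause was not tested. With only the 2 groups compared limma called 0, with 298 genes at an unadjusted p under 0.05, in a fit on fewer samples. With only the 2 groups compared, R1 against MMS D14 in cartilage had 467 called genes, more than with all groups, and the cause was not tested. Between R2 and R1 in synovium, leaving out the library set gave 14 called genes, and the cause was not tested.

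Leaving out each library in turn gave ranges of counts from fewer samples. Against Control, synovium counts were 484 to 679 in MMS D3, 931 to 987 in MMS D7, 1122 to 1137 in MMS D14, 625 to 676 in R1 and 554 to 751 in R2. Against MMS D14 they were 957 to 1068 in R1 and 956 to 1045 in R2. In cartilage, a left-out library leaves its group with 1 sample, and the lone sample is assumed to vary like the other groups. Cartilage counts against Control were 126 to 206 in MMS D3, 197 to 327 in MMS D7, 502 to 714 in MMS D14, 1319 to 1512 in MMS D28, 536 to 799 in R1 and 0 to 17 in R2, where the lowest came with 168 genes at an unadjusted limma p under 0.05. Against MMS D14 they were 117 to 170 in R1 and 345 to 440 in R2. In synovium no such count moved by more than 1.5 times. Depth is unknown, so its effect on these results could not be examined.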

Other observations

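The splits of the samples were planned, and every other value in this part was chosen after the result was seen.

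Each synovium comparison was repeated on the other splits of its 6 samples into 3 and 3, which number 10 with the real one. In each, 1 split, the real one, gave as many genes. The real counts by limma were 659 in MMS D3, 1010 in MMS D7, 1142 in MMS D14, 720 in R1 and 716 in R2 against Control, and 1049 and 1042 in R1 and R2 against MMS D14. The highest count of any other split was 1, in MMS D14 against Control and in R1 against MMS D14, and no gene was called in the others. With 10 splits a share under 0.05 cannot be reached. The other splits also mix the 2 groups compared, so a difference between them widens the spread, and the genes were selected. Low counts in those splits therefore do not speak against chance. Across all 6 groups, 1156 genes differed, and 1 of 100 drawn splits, the real one, gave as many, with 744 in the highest of the others. The tested genes were selected, nearly all with a difference between MMS D14 and Control, so this says nothing about chance as the source of that count.

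In cartilage, the medians of B cell and neutrophil genes had opposite signs in MMS D14, MMS D28 and R1 and the same sign in the other groups, and the difference was not tested. The 6 B cell genes had median log2 changes against Control of -0.62 in MMS D3, -1.48 in MMS D7, -1.68 in MMS D14, -1.96 in MMS D28, -1.07 in R1 and 0.33 in R2. The 13 neutrophil genes had -0.10, -0.23, 0.45, 0.88, 0.81 and 0.15 in the same order of groups. Cartilage itself expresses neither set in quantity, so marrow or blood in the tissue taken is a candidate source of these transcripts. Whether the composition of marrow differed between groups, or the marrow spaces reached in taking the tissue, was not tested, and the median of the B cell genes of -1.68 in MMS D14 speaks only against more marrow cells of all kinds.

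Single libraries stood out in some genes. Egln3, a hypoxia-induced hydroxylase gene, was 37.0 FPKM in synovium R1 replicate 2, the library with the high Retnla value. Pygm, a muscle glycogen phosphorylase gene, was 62.1 FPKM in synovium MMS D14 replicate 3 and 24.7 in Control replicate 2. Mylpf, a fast muscle myosin gene, had a signal of 90.3 in cartilage Control replicate 2 and 15.3 in replicate 1.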
